A study of Mus musculus with 30 samples.

How the data were processed

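Kidney, brain and heart of the same 10 male C57BL/6JRj mice were profiled on Illumina BeadChip arrays, with 1 array per tissue and mouse. Mouse identifiers in the sample labels linked the 3 tissues. Per the labels, RNA was extracted with Trizol and RNeasy, biotin-labelled cRNA was made with the Ambion MessageAmp kit, and mice were assigned at random to rapamycin or vehicle. The submitters' processing notes name GenomeStudio 2011.1, and other steps of scanning and summary were not given in the sources used here.

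The deposited non-normalized file held, per the file headers, a signal intensity for each probe and array on a linear scale, with no normalization between arrays and no background subtracted. Per the file headers it also held a detection p-value for each probe and array, which compares the probe with the negative control beads of its array. A second deposited matrix by the authors held background-subtracted intensity on a linear scale. Its arrays had nearly equal distributions (medians 11.71 to 12.07, lower quartiles -0.132 to -0.006857, upper quartile 106.1), and the normalization behind it was not given in the sources used here. The non-normalized intensities were used for the main tests and the second matrix as an alternative.

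Groups followed the source name and the stated age of each sample. The titles conflicted with these, because they marked the 25-month controls as young. Grouping by title was run as an alternative, and genes with a known age difference, fixed beforehand, were read as a check of the labels. Of 25697 probes, 23978 carried 1 gene symbol, 0 carried several and 1719 carried none. Entrez identifiers of 23962 probes matched the RefSeq genes, which changed 0 symbols, and 16593 distinct symbols remained. Where a gene had several probes, the one with the highest mean signal in the tissue stood for it.

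Within each tissue, intensities were background-corrected with normexp, using negative control parameters inferred from the detection p-values and an offset of 16, quantile-normalised and put on a log2 scale (neqc, limma 3.58.1 in R 4.3.3, with the data.table package, version 1.17.8). Probes with a detection p-value under 0.05 on at least 2 of the 10 arrays of a tissue were tested. A linear model with 1 mean per group was fitted to all 10 arrays of a tissue and moderated with limma's empirical Bayes step, so that the 2 old controls shared the spread of the other groups. The contrasts were old control minus young control, rapamycin minus old control, and rapamycin minus young control, at a Benjamini-Hochberg adjusted p under 0.05 over all tested probes. Errors after ± are standard errors from limma. Arrays give no counting depth, so the number of arrays limits the precision. Differences of an effect between tissues were tested in limma over 30 arrays normalised together, with the mouse as a random effect.

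The 53 gene lists, fixed in advance, covered immune and other cell types, parts of each organ, and stress, metabolic and mTOR-related pathways. Lists can share members, as the macrophage and complement lists do, so their results are not independent. They were tested with camera at a preset correlation between genes of 0.01, with an estimated correlation as the alternative, and adjusted over the lists of a comparison. Genes named in the text were drawn from a pool set by a rule: the 12 largest rises and falls past the test for age and rapamycin, and 5 for rapamycin against young. With fewer than 6 passing genes, all of them and the 5 with the smallest p were taken. Up to 4 passing members of each called list (or 2 with the smallest p if none passed), Mtor and Fkbp1a, and the label check genes were added to the pool. Only part of this pool is named in the text, and no rule was set for that part. For a gene detected on no array of a group, only a lower bound of its fold was given.

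Groups, tests, gene lists, the naming rule and the other settings to be tried were chosen before the data were examined. Leaving out the kidney array of rapamycin mouse 2 was chosen after its signal was seen. Alternatives covered background correction, median scaling, normalization over all arrays, the authors' matrix, stricter and no detection filters, a variance trend with robust moderation, array weights, the arrays of the compared groups alone, the replicate number as a block, grouping by title and leaving out each mouse. A block for the BeadChip slide was not run, since the files used here carry no chip identifiers. The tests were also tried on simulated data with the spread of each tissue, where 3.23% to 5.73% of calls were false. Each draw had 200 changed probes, genes drawn independently and 1 spread per probe for all groups. A comparison with fewer real changes has a stricter threshold, so the share found may be lower there.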

Results

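Gene expression was measured in kidney, brain and heart of 10 male C57BL/6JRj mice on Illumina BeadChip arrays with 25697 probes. Every mouse gave all 3 tissues, so the data comprised 30 arrays, 1 per tissue and mouse. Each tissue had 4 control mice aged 25 weeks, 2 control mice aged 25 months and 4 mice aged 25 months that had received rapamycin, an inhibitor of mTOR complex 1. Treatment of this cohort started at 13 months of age and lasted more than 12 months according to the labels. Probes detected above background numbered 9989 to 12777 per array in kidney, 12975 to 13562 in brain and 11923 to 12686 in heart. The lowest of these counts belonged to the kidney array of rapamycin mouse 2, and the other 9 kidney arrays had 11962 to 12777. Median signal intensity before normalization was 100.8 on that array and 117.5 to 130.7 on the other kidney arrays. Its median correlation with the other kidney arrays across probes was 0.8585, against 0.9823 to 0.9921 for the others. Kidney comparisons are therefore given with all 10 arrays and, as a choice made after this was seen, with the other 9.

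**Figure D1:**
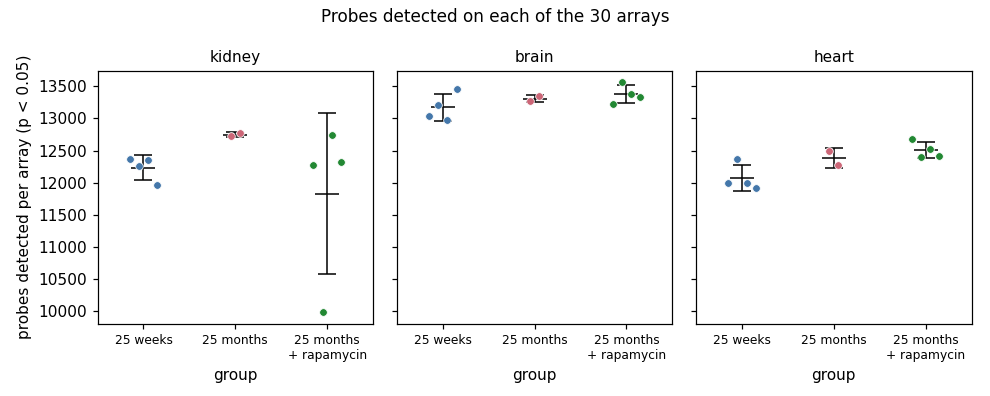
Probes detected at a detection p-value under 0.05 on each of the 30 arrays (points), by tissue and group, with the mean and SD of each group (black; n = 4, 2 and 4). The kidney array of rapamycin mouse 2 had 9989 detected probes and the other kidney arrays 11962 or more.

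Sample titles and age labels disagreed for the controls: the titles marked the 25-month controls as young. The stated ages were used, and genes fixed beforehand as known to be higher in old mouse tissue were read as a check. In brain, C4b, which encodes complement component 4, was higher in the mice labelled 25 months than in those labelled 25 weeks by log2 2.23 ± 0.12 (SE; n = 2 and 4; adjusted p = 1.51e-06). Lyz2, the lysozyme of macrophages and microglia (log2 1.70 ± 0.16), and Gfap, the intermediate filament of astrocytes (1.06 ± 0.16), were also higher there. In heart, C4b (1.95 ± 0.22) and the alarmin Il33 (0.94 ± 0.19) were higher in the mice labelled 25 months. In total 3 of 7 check genes passed in brain, 2 of 6 in heart and 0 of 5 in kidney with all arrays, where C4b differed by log2 1.57 ± 0.54 (adjusted p = 0.534). In kidney without the array of rapamycin mouse 2, C4b and Lyz2 passed, although both lost their call with 25-month control 1 left out. With each mouse left out in turn C4b and Lyz2 passed in brain every time, while Gfap did not without either 25-month control (adjusted p = 0.0653 and 0.0906), and in heart neither C4b nor Il33 passed without 25-month control 1 (0.066 and 0.805).

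The first kidney comparison asked which transcripts differ between control mice of 25 months and 25 weeks. Here and in every other age comparison, age cannot be told apart from other differences between these groups of mice. The hour of tissue collection, for example, was not given in the sources used here. Kynu, which encodes the tryptophan-degrading enzyme kynureninase, rose 10.7-fold in the old mice (log2 3.42 ± 0.48; SE; n = 2 and 4; adjusted p = 0.0375). The chemokine genes Ccl8 (log2 3.15 ± 0.45) and Cxcl13 rose too, the latter at least 3.53-fold because no young array detected it. The aldehyde dehydrogenase Aldh1a1 (2.54 ± 0.30), the carbonyl reductase Cbr3 (3.36 ± 0.40) and the epoxide hydrolase Ephx1 (1.61 ± 0.22) rose, as did Ms4a6d, expressed in macrophages (2.41 ± 0.34), and the clock output gene Dbp (1.60 ± 0.22). Akr1c18, an enzyme that inactivates progesterone, fell by log2 2.82 ± 0.27 (adjusted p = 0.0151). These were among 13 probes past the limma test, 12 higher and 1 lower in old mice, of 13805 tested, and 875 had an unadjusted p under 0.05. None of these 9 genes passed without 25-month control 1, and each was also lost without several young mice.

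Among 19 macrophage markers the median log2 age difference in kidney was 1.08, and none passed over all genes while 11 were higher when adjusted over the list alone (camera adjusted p = 7.65e-15, and adjusted p = 0.0323 with an estimated correlation). C1qa, a subunit of complement C1q and a macrophage marker, differed by 1.28 ± 0.24. Complement genes had a median of 1.25, with 0 of 9 higher over all genes and 7 when adjusted over the list alone (adjusted p = 6.3e-10, and 0.0323 with an estimated correlation). Genes of kidney injury had a positive difference in all 17 measured members, with 0 higher over all genes and 3 when adjusted over the list alone (adjusted p = 1.25e-09, and 0.0323 with an estimated correlation). Vcam1, an endothelial and tubular adhesion molecule, differed by 1.79 ± 0.27 and the tubular injury marker Havcr1 by 1.36 ± 0.24 among them. Interferon response genes had a median of 0.88, with 0 of 26 higher over all genes and 9 when adjusted over the list alone (adjusted p = 2.12e-15). That call was lost at adjusted p = 0.112 with an estimated correlation, and the median was 0.459 without 25-month control 1. Proximal tubule genes pointed downward (median -0.29, 0 of 23 past the test over all genes, 5 lower and 1 higher when adjusted over the list alone, adjusted p = 0.000511, and 0.0323 with an estimated correlation). Slc22a6, a basolateral organic anion transporter of that segment, differed by -0.81 ± 0.19. The kidney count of 13 fell to 0 without 25-month control 1 and rose to 21 without control 2. It was 1 without young mouse 1 and 0 without young mouse 2, 3 or 4. Rapamycin mice enter this comparison only through the shared spread, the normalization and the detection filter. Leaving out 1 of them gave 2, 1315, 4 and 0 for mice 1 to 4. With median scaling in place of quantile normalization 1 probe passed, 0 higher and 1 lower.

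Without the kidney array of rapamycin mouse 2, the age comparison gave 1315 probes of 13651, 728 higher and 587 lower. Among the largest rises, the glutathione transferase Gsta1 was at least 7.22-fold higher, and Gsta2 (log2 2.44 ± 0.34), Cbr1 (2.36 ± 0.34) and the fatty acid hydroxylase Cyp4a14 (3.08 ± 0.60) rose as well (SE; n = 2 and 4). The list of NRF2 and antioxidant genes had 10 members higher and 1 lower of 26, and 12 and 5 when adjusted over the list alone (adjusted p = 0.0055, and adjusted p = 0.213 with an estimated correlation). Lcn2, an iron-binding protein of neutrophils and injured tubules, rose by 2.78 ± 0.38 and the neutrophil gene S100a8 by 2.82 ± 0.50. Of the macrophage list 13 of 19 genes rose, and 15 when adjusted over the list alone, with Lyz2 at 2.19 ± 0.35 and C1qb at 1.47 ± 0.20 (adjusted p = 4.39e-11, and adjusted p = 0.242 with an estimated correlation). Kidney injury genes numbered 9 higher of 17, and 10 when adjusted over the list alone, with Havcr1 at 1.40 ± 0.21 and the cell cycle inhibitor Cdkn1a, from the p53 target list, at 0.96 ± 0.18 (injury list adjusted p = 1.56e-09, and adjusted p = 0.242 with an estimated correlation). Proximal tubule genes split into 2 higher and 9 lower of 23, and 3 and 11 when adjusted over the list alone (adjusted p = 3e-04, and adjusted p = 0.213 with an estimated correlation). The acyl-CoA synthetase Acsm3 fell by 3.06 ± 0.55 and the anion transporter Slc22a7 by 2.10 ± 0.25, while Hpd of tyrosine breakdown rose by 1.58 ± 0.32. Mtor, the kinase that rapamycin acts on through Fkbp1a, fell by 0.96 ± 0.17 in old mice (adjusted p = 0.00891). The count was 87 without 25-month control 1, where S100a8 differed by 1.62, Acsm3 by -1.81 and Cdkn1a by 0.61 (adjusted p = 0.066, 0.0961 and 0.143) and Gsta1 had a fitted value of 2.00 instead of 3.35 (adjusted p = 0.0134), and it was 738 and 735 without young mice 2 and 4. Without that control Cyp4a14, Lyz2, Havcr1, Hpd and Mtor did not pass either (adjusted p = 0.162, 0.0915, 0.0912, 0.222 and 0.148), while Gsta1, Gsta2, Cbr1, Lcn2, C1qb and Slc22a7 passed with each of the 9 mice left out in turn. Median scaling gave 1295 probes, of which 907 were higher and 388 lower.

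The second kidney comparison set rapamycin-treated against control mice of 25 months. Per the labels, mice were assigned at random to rapamycin or vehicle. With all arrays limma called 0 of 13805 probes, 418 had an unadjusted p under 0.05, and the smallest adjusted p was 0.825. The 5 genes with the smallest p, none of which passed, included Cbr3 (log2 difference -1.83 ± 0.40; SE; n = 4 and 2), the glycolytic aldolase gene Aldoc (-1.10 ± 0.24) and the phospholipase gene Pla1a (-1.18 ± 0.24), lower in treated mice, and the mitochondrial GTPase gene Mtg2 (0.76 ± 0.17), higher. Mice given rapamycin showed higher values in 24 of 29 extracellular matrix genes (median 0.53; 0 higher over all genes and 0 when adjusted over the list alone; adjusted p = 1.53e-05, and adjusted p = 0.383 with an estimated correlation), including Col15a1 (0.83 ± 0.22) and Col1a1 (0.97 ± 0.35). Lower values were seen in 52 of 68 oxidative phosphorylation genes (median -0.24; adjusted p = 2.35e-05, and 0.383 with an estimated correlation) and in 17 of 21 genes of the thick limb and distal segments (median -0.53; adjusted p = 1.36e-05, and 0.445 with an estimated correlation), such as Egf (-1.37 ± 0.39). In neither list did a gene pass over all genes or when adjusted over the list alone. Without the low array the medians of these 3 lists were 0.344, -0.125 and -0.105. There limma again called 0 probes, 1608 had an unadjusted p under 0.05, and the smallest adjusted p was 0.171. The sodium-phosphate cotransporter gene Slc34a3 differed by -0.84 ± 0.14 and the potassium channel gene Kcnj1 by -0.80 ± 0.13 there. Extracellular matrix genes then had 26 of 28 positive values and 11 higher when adjusted over the list alone, against 0 over all genes (adjusted p = 8.14e-07, and adjusted p = 0.639 with an estimated correlation). The count became 2 when 25-month control 2 was left out of all arrays, and from the 9 arrays it became 79 without 25-month control 2 and 155 without rapamycin mouse 1. Simulated data of this design had 200 changed probes, so the threshold there was less strict than in this comparison. A change of log2 2 was found for 69.7% of probes with all arrays and 97.9% with 9, and one of log2 1 for 24.8% and 79.4%. With median scaling the median of all probes in this comparison was log2 -0.123, against 0.00722 with quantile normalization.

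The third kidney comparison set the treated 25-month mice against the 25-week controls. Havcr1 rose by log2 2.16 ± 0.20 (SE; n = 4 and 4; adjusted p = 0.00505), Vcam1 by 2.09 ± 0.22, Lcn2 by 2.46 ± 0.41, C1qa by 1.53 ± 0.19 and the complement regulator Cfi by 1.94 ± 0.28. Kynu (2.71 ± 0.39), Aldh1a1 (2.37 ± 0.25), the matrix proteoglycan Dcn (1.04 ± 0.16) and Tsc22d3, a glucocorticoid-induced gene (1.12 ± 0.19), were higher as well. Akr1c18 was at least 5.73-fold lower, since no treated array detected it, and Lpl, the lipoprotein lipase, fell by 1.11 ± 0.14. The cortisone reductase Hsd11b1 fell by 1.30 ± 0.20, with 2 of its 4 probes past the test. Of 13805 probes 51 passed, 41 higher and 10 lower in treated mice. Macrophage markers had 2 of 19 genes higher and 15 when adjusted over the list alone (adjusted p = 2.69e-13, and 0.0459 with an estimated correlation). Kidney injury genes had 3 of 17 and 11 (adjusted p = 9.41e-10, and 0.0367 with an estimated correlation), and complement genes 2 of 9 and 8 when adjusted over the list alone (adjusted p = 9.95e-10, and 0.0367). Extracellular matrix genes had 1 of 29 higher and 13 when adjusted over the list alone (adjusted p = 1.59e-08, and adjusted p = 0.0983 with an estimated correlation). Akr1c18 and Havcr1 passed with each mouse left out in turn, and the other 10 genes named so far did not. The count was 4, 2, 2 and 6 without young mice 1 to 4, and 1156, 16 and 3 without rapamycin mice 2, 3 and 4. Of the 1156 probes of the 9 arrays 725 were higher and 431 lower. There the thyroid hormone carrier gene Ttr fell by 2.19 ± 0.18, Slc34a3 fell by 1.47 ± 0.11 and the metalloproteinase inhibitor gene Timp1 rose by 1.90 ± 0.24, and all 3 passed with each of the 9 mice left out in turn. Extracellular matrix genes then had 13 of 28 higher and 20 when adjusted over the list alone (adjusted p = 1.22e-11, and adjusted p = 0.234 with an estimated correlation). The 1156 became 656, 551, 709 and 701 without young mice 1 to 4 and 2318, 431 and 518 without rapamycin mice 1, 3 and 4. With median scaling the 9 arrays gave 1427, 1185 higher and 242 lower.

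In the brain age comparison C4b rose by log2 2.23 ± 0.12 (SE; n = 2 and 4; adjusted p = 1.51e-06) in 25-month controls. Gpnmb, a glycoprotein of lipid-laden phagocytes (1.95 ± 0.17), the galectin Lgals3 (1.89 ± 0.20), Lyz2 (1.70 ± 0.16), Lyz1 (1.66 ± 0.13) and Cd52 (1.22 ± 0.09) rose with it. S100a8 (2.90 ± 0.55), S100a9 (2.41 ± 0.48), Lcn2 (2.77 ± 0.59) and the lactoferrin gene Ltf (1.71 ± 0.29), all products of neutrophils, were higher too. Without 25-month control 1 they differed by 2.08, 1.52, 1.42 and 1.29 in that order, and none passed (adjusted p = 0.344, 0.424, 0.446 and 0.269), and S100a8, S100a9 and Lcn2 passed in 7, 6 and 3 of the 10 fits with a mouse left out. Among falls were the synaptic pentraxin Nptx2 (fell by 0.93 ± 0.16), the activin subunit Inhba (fell by 0.92 ± 0.12) and the histone H3 genes H3c4 (fell by 0.76 ± 0.11) and H3c6 (fell by 0.65 ± 0.11). Ch25h, which makes the sterol 25-hydroxycholesterol, was at least 2.66-fold higher. Leaving out 25-month control 1 left 0 probes lower, and Nptx2, Inhba, H3c4 and H3c6 did not pass (adjusted p = 0.13, 0.0892, 0.119 and 0.255), nor did Nptx2 and H3c6 without control 2 (0.132 and 0.0527). C4b, Gpnmb, Lgals3, Lyz2, Lyz1, Cd52 and Ch25h passed with each mouse left out in turn. Leaving out 1 of the 2 old controls widens the error of the fit, so a lost call alone need not mean a smaller difference. In all, 123 of 14473 probes passed, 104 higher and 19 lower.

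By list, 12 of 20 macrophage and microglia genes rose with age in brain, and 16 when adjusted over the list alone (adjusted p = 5.44e-28, and 0.015 with an estimated correlation). Of the complement genes 4 of 7 rose, among them C1qa (0.70 ± 0.13), C1qb (0.62 ± 0.09) and C1qc (0.65 ± 0.10), and 5 when adjusted over the list alone (adjusted p = 4.33e-09, and 0.015 with an estimated correlation). C1qa, C1qb and C1qc also belong to the macrophage and microglia list. Interferon response genes had 10 of 22 higher, and 14 when adjusted over the list alone, with the antiviral enzyme Oasl2 at 1.29 ± 0.17 and Usp18, which removes ISG15 from proteins, at 1.13 ± 0.17 (adjusted p = 3.77e-15, and 0.036 with an estimated correlation). Neutrophil genes had 7 of 10 higher and 8 when adjusted over the list alone (adjusted p = 3.74e-12, and adjusted p = 0.153 with an estimated correlation), with a median of 1.36 that became 1.08 without 25-month control 1 and 2.09 without control 2. Antigen presentation by MHC class I had 2 of 13 higher and 8 when adjusted over the list alone, with B2m at 0.69 ± 0.12 (adjusted p = 2.87e-07, and adjusted p = 0.153 with an estimated correlation). The astrocyte list had 2 of 17 higher, Gfap (1.06 ± 0.16) and the serpin Serpina3n (1.60 ± 0.14), and 5 higher and 2 lower when adjusted over the list alone (adjusted p = 0.0235, and adjusted p = 0.153 with an estimated correlation). Neuronal and synaptic genes had 0 of 30 past the test over all genes and 2 lower when adjusted over the list alone (adjusted p = 0.0309, and adjusted p = 0.153 with an estimated correlation). Fits without 1 old control have a wider error, so a call lost there need not mean a smaller difference. Of the genes named for these lists, Serpina3n passed with each mouse left out, C1qa, C1qb, C1qc and Gfap did not pass without control 1 (adjusted p = 0.283, 0.117, 0.0928 and 0.0653) or control 2 (0.116, 0.0646, 0.0717 and 0.0906), C1qa did not without young mouse 2 or 4 either, B2m did not without control 1 (0.269), and Oasl2 and Usp18 did not without control 2 (0.0512 and 0.099). The brain count was 23 without 25-month control 1, all higher, 57 without control 2, and 70, 79 and 81 without young mice 2, 3 and 4.

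Rapamycin-treated and control brains of 25 months differed at 4 of 14473 probes, 1 higher and 3 lower with treatment, and 1422 had an unadjusted p under 0.05. The lower ones were the renal phosphate transporter gene Slc34a1 (at least 1.64-fold; adjusted p = 0.000441), the trypsin inhibitor gene Spink1 (at least 2.10-fold; adjusted p = 0.0398) and Prg2, an eosinophil granule protein (at least 1.89-fold; adjusted p = 0.00248). All 3 were detected on both 25-month control arrays and on no treated or young brain array. On the same 2 arrays 30 other transcripts abundant in kidney had a median rise of log2 0.209 and 0.0919 over the brain median, and the highest of the other 8 brain arrays had -0.00142. These 30 were limited to probes detected on at most 2 brain arrays. The 1 probe higher with treatment belonged to Cdkn1a, and the probe with the highest mean signal of its 3 differed by 0.90 ± 0.15 (SE; n = 4 and 2; adjusted p = 0.0962). Neutrophil genes were lower in all 10 measured members (median log2 -0.95), with 0 past the test over all genes and 7 when adjusted over the list alone (adjusted p = 3.53e-09, and adjusted p = 0.267 with an estimated correlation). Their median was -0.404 without 25-month control 1 and -1.67 without control 2. Camp, an antimicrobial peptide of neutrophil granules, differed by -1.08 ± 0.25. Glucocorticoid-responsive genes were positive in 16 of 16 (median 0.30; 0 over all genes and 5 when adjusted over the list alone; adjusted p = 1.01e-05, and adjusted p = 0.267 with an estimated correlation). Choroid plexus genes were negative in 11 of 11 (median -0.33; 0 and 4 when adjusted over the list alone; adjusted p = 1.11e-06, and adjusted p = 0.267 with an estimated correlation). Olfactory bulb genes were positive in 7 of 7 (median 0.41; 0 and 5 when adjusted over the list alone; adjusted p = 3.95e-05, and adjusted p = 0.267 with an estimated correlation). Without 25-month control 2 the medians of the glucocorticoid, choroid plexus and olfactory bulb lists were 0.169, -0.218 and 0.263. Cdhr1, a gene of olfactory bulb neurons, was at log2 5.92 to 8.30 on the control arrays and 8.26 to 8.91 on the treated ones. For the lists of brain regions, an effect of treatment cannot be told apart from differences in which parts of the brain each sample held. Mtor differed by 0.17 ± 0.09 (adjusted p = 0.567). The count was 0 and 2 without 25-month controls 1 and 2, where 0 of the 4 probes were called again, 21, 2, 2 and 2 without rapamycin mice 1 to 4, and 2 without young mouse 2 or 4. The 3 lower genes left the detection filter without either control, and with the filter of all arrays kept Slc34a1 and Prg2 passed without each control, but Spink1 did not without control 1 (log2 -0.85; adjusted p = 0.0748), a fitted 1.80-fold that lies under the bound above. Spink1 also did not pass without any young mouse or rapamycin mouse 2, 3 or 4. Median scaling gave 20 probes, 10 higher and 10 lower. With 200 changed probes in simulated data, a change of log2 1 was found for 93.7% of probes here and one of log2 0.5 for 49.3%. The real comparison called 4 probes, so its threshold was stricter.

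Against 25-week brains, treated 25-month brains had higher C4b (log2 2.12 ± 0.10; SE; n = 4 and 4; adjusted p = 2.23e-07), Lgals3 (1.94 ± 0.17), Gpnmb (1.87 ± 0.14), Lyz1 (1.65 ± 0.11), Serpina3n (1.47 ± 0.11), Gfap (1.23 ± 0.13) and Trem2, the lipid-sensing receptor of microglia (0.80 ± 0.08). The heat shock protein gene Hspa4l fell by 0.80 ± 0.15, Gpr17, a receptor of oligodendrocyte precursors, by 0.58 ± 0.12, H3c4 fell by 0.60 ± 0.09 and H3c6 fell by 0.59 ± 0.09. Of 14473 probes 158 passed, 131 higher and 27 lower. Macrophage and microglia genes had 13 of 20 higher, and 16 when adjusted over the list alone (adjusted p = 2.92e-30, and 0.00802 with an estimated correlation). Complement had 5 of 7 higher and 6 when adjusted over the list alone (adjusted p = 1.8e-12, and 0.00802 with an estimated correlation), and the interferon response 8 of 22 and 18 (adjusted p = 4.66e-18, and 0.022). Lysosomal genes had 3 of 35 higher, including the cathepsin Ctsz (0.58 ± 0.09), and 6 when adjusted over the list alone (adjusted p = 0.000406, and adjusted p = 0.204 with an estimated correlation). Hspa4l and Gpr17 passed in 4 and 1 of the 10 fits with a mouse left out, and the other 10 genes named passed in each. The count was 93, 68 and 87 without young mice 1, 2 and 3, and 440, 96, 62 and 86 without rapamycin mice 1 to 4.

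In heart, S100a8 rose 16.2-fold in 25-month controls (log2 4.02 ± 0.59; SE; n = 2 and 4; adjusted p = 0.00951) and its partner S100a9 by 3.52 ± 0.53, while the neutrophil gene Retnlg was at least 4.04-fold higher. The chemokines Ccl8 (3.70 ± 0.28) and Cxcl13 (2.41 ± 0.27), C4b (1.95 ± 0.22) and the matrix metalloproteinase Mmp3 (1.59 ± 0.21) rose too. So did Myh7, the myosin heavy chain of slow muscle and the fetal ventricle (1.89 ± 0.36), and the potassium channel gene Kcnk1 (1.89 ± 0.16). Clock genes Dbp (2.26 ± 0.28), Ciart (2.00 ± 0.26) and Per2 (1.58 ± 0.30) were higher. Angptl4, an inhibitor of lipoprotein lipase, fell by 2.64 ± 0.31 and Pdk4, which blocks entry of pyruvate into the citric acid cycle, fell by 1.96 ± 0.28. Without 25-month control 1 the difference was 2.64 for S100a8 and 2.25 for S100a9 (adjusted p = 0.11 for both) and 1.16 for Myh7 (adjusted p = 0.676), and the fitted value of Retnlg was 1.25 instead of 2.45 (adjusted p = 0.413). Cxcl13, C4b, Mmp3, Dbp, Ciart, Per2, Angptl4 and Pdk4 did not pass without that mouse either (adjusted p = 0.0707, 0.066, 0.066, 0.113, 0.144, 0.761, 0.05 and 0.11), and 0 probes were lower. Ccl8 and Kcnk1 passed with each mouse left out in turn, and Myh7, Retnlg and Per2 in 3, 3 and 5 of these 10 fits. A fit without 1 of the 2 old controls has a wider error, so a lost call need not mean a smaller difference. Angptl4 was at 6.858 and 6.358 on the arrays of controls 1 and 2, so its fall was not smaller without control 1. Of 13773 probes 86 passed, 73 higher and 13 lower.

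Among heart lists, interferon response genes had 2 of 27 higher with age and 16 when adjusted over the list alone (median 0.63; adjusted p = 1.81e-14, and adjusted p = 0.186 with an estimated correlation). Macrophage genes had 2 of 19 and 11 (median 0.67; adjusted p = 2.46e-11, and adjusted p = 0.156 with an estimated correlation), with the IgG receptor gene Fcgr3 at 1.00 ± 0.15. Neutrophil genes had 3 of 6 higher and 6 when adjusted over the list alone (median 1.81; adjusted p = 3.05e-09, and adjusted p = 0.156 with an estimated correlation). Complement had 1 of 9 and 8 when adjusted over the list alone (adjusted p = 3.28e-09, and adjusted p = 0.156 with an estimated correlation). Fatty acid oxidation genes had 2 of 28 lower, Angptl4 and Pdk4, and 8 when adjusted over the list alone (adjusted p = 0.000708, and adjusted p = 0.137 with an estimated correlation). Both are regulators under fatty acid sensing receptors rather than enzymes of the oxidation cycle. Cytosolic heat shock genes had 1 of 17 lower, the cochaperone Fkbp4 (fell by 0.68 ± 0.13), and 9 when adjusted over the list alone (adjusted p = 2.07e-05, and adjusted p = 0.156 with an estimated correlation). Circadian clock genes had 3 of 16 higher, and 5 higher and 2 lower when adjusted over the list alone (adjusted p = 0.000751, and adjusted p = 0.257 with an estimated correlation). Without 25-month control 1 the medians of the interferon, macrophage and neutrophil lists were 0.372, 0.434 and 1.25, and that of the neutrophil list was 3.64 without control 2. The fall of Angptl4 was not smaller without control 1, as its levels were 6.858 and 6.358 in controls 1 and 2. Fcgr3, Fkbp4, Angptl4 and Pdk4 did not pass without control 1 (adjusted p = 0.262, 0.778, 0.05 and 0.11), and Fkbp4 passed in 3 of the 10 fits with a mouse left out. The heart count was 5 without 25-month control 1 and 214 without control 2, and it was 53, 39 and 34 without young mice 1, 3 and 4.

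Between treated and control 25-month hearts limma called 0 of 13773 probes, 1598 had an unadjusted p under 0.05, and the smallest adjusted p was 0.1405. The 5 genes with the smallest p, none of which passed, were the myosin light chain kinase gene Mylk (0.87 ± 0.14; SE; n = 4 and 2), the endothelial receptor gene Tie1 (0.89 ± 0.15) and the actin-bundling gene Fscn1 (1.20 ± 0.21), with higher values in treated mice, and Gpnmb (-0.76 ± 0.13) and the kallikrein gene Klk1b26 (-1.02 ± 0.17), with lower ones. Glucocorticoid-responsive genes were positive in 15 of 16, with Pdk4 at 1.23 ± 0.28 and Arrdc2 at 0.93 ± 0.21 (median 0.43; 0 higher over all genes and 9 when adjusted over the list alone; adjusted p = 7.7e-07, and adjusted p = 0.642 with an estimated correlation). Neutrophil genes were negative in 6 of 6, with S100a9 at -1.53 ± 0.53 (median -1.19; 0 lower over all genes and 5 when adjusted over the list alone; adjusted p = 0.000218, and adjusted p = 0.642 with an estimated correlation). Interferon response genes were negative in 24 of 27, with Gbp2 at -0.96 ± 0.32 (median -0.31; 0 over all genes and 0 when adjusted over the list alone; adjusted p = 0.000133, and adjusted p = 0.907 with an estimated correlation). Without 25-month control 1 the medians of the neutrophil and interferon lists were -0.115 and -0.0253, and without control 2 they were -2.48 and -0.519, where S100a9 differed by -2.80 (-0.27 without control 1). Atrial genes were positive in 13 of 15, with Myl7 at 0.92 ± 0.20 (0 over all genes and 5 when adjusted over the list alone; adjusted p = 0.000133, and adjusted p = 0.642 with an estimated correlation). Adipocyte genes were positive in 8 of 8, and Ucp1 of brown fat was detected on no 25-month control array, on all 4 treated ones and on all 4 young ones (0 over all genes and 2 when adjusted over the list alone; adjusted p = 0.0006, and adjusted p = 0.642 with an estimated correlation). Mtor differed by 0.49 ± 0.17 (adjusted p = 0.336). The count was 36 without 25-month control 2 and 1 without rapamycin mouse 2. With 200 changed probes in simulated data, changes of log2 1 and 2 were found for 76.4% and 97.9% of probes. The real comparison called 0 probes, so its threshold was stricter.

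Gene lists tied to the drug's target were read in the same rapamycin comparisons. Components of the mTOR pathway had median log2 differences of 0.07 in kidney, 0.07 in brain and -0.04 in heart, and limma called 0 of 31, 31 and 30 over all genes and 0, 0 and 1 when adjusted over the list alone (camera adjusted p = 0.738, 0.111 and 0.782). Autophagy genes had medians of -0.01, -0.06 and -0.03, with 0 called over all genes in each tissue and 0, 0 and 1 when adjusted over the list alone (adjusted p = 0.748, 0.722 and 0.782). Ribosome biogenesis genes had medians of 0.23, -0.01 and -0.02, with 0 called either way (adjusted p = 0.404, 0.771 and 0.972). Cytosolic ribosomal protein genes in kidney were lower in 34 of 53 (median -0.10, 0 called over all genes and 0 when adjusted over the list alone, camera adjusted p = 0.044, and adjusted p = 0.8 with an estimated correlation). Without some mouse this median moved by over 1.5 times or changed sign, as for all 13 lists called in that comparison.

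Treated 25-month hearts compared with 25-week hearts had higher S100a8 (log2 2.38 ± 0.48; SE; n = 4 and 4; adjusted p = 0.0416), Ccl8 (2.26 ± 0.23), Cxcl13 (2.09 ± 0.22) and C4b (1.44 ± 0.18). MHC class II genes rose, among them H2-Eb1 (1.32 ± 0.21), H2-Ab1 (1.27 ± 0.26) and the invariant chain Cd74 (1.21 ± 0.23), 3 of 8 over all genes and 6 when adjusted over the list alone (adjusted p = 7.75e-07, and adjusted p = 0.226 with an estimated correlation). Clock genes had 4 of 16 higher, Dbp (1.92 ± 0.23), Ciart (1.68 ± 0.21), Per2 (1.42 ± 0.24) and Per1 (1.31 ± 0.21), and 2 lower, Nfil3 (fell by 0.99 ± 0.20) and Arntl (fell by 0.97 ± 0.19), with 10 higher and 2 lower when adjusted over the list alone (adjusted p = 1.7e-05, and adjusted p = 0.226 with an estimated correlation). Angptl4 fell by 1.45 ± 0.26 and the thioesterase gene Acot1 fell by 0.92 ± 0.16, the 2 of 28 fatty acid oxidation genes that passed, and 10 were lower when adjusted over the list alone (adjusted p = 0.000169, and adjusted p = 0.0894 with an estimated correlation). Of 13773 probes 130 passed, 105 higher and 25 lower. Median scaling gave 255, 242 higher and 13 lower, with a median of all probes of log2 0.106 against -0.00486. Ccl8, Cxcl13, C4b, Dbp and Ciart passed with each mouse left out in turn, and the other 10 genes named did not. The count was 34, 30 and 30 without young mice 1, 3 and 4, with 0 lower without mouse 3 or 4, and 66, 267 and 32 without rapamycin mice 1, 2 and 3.

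**Figure D2:**
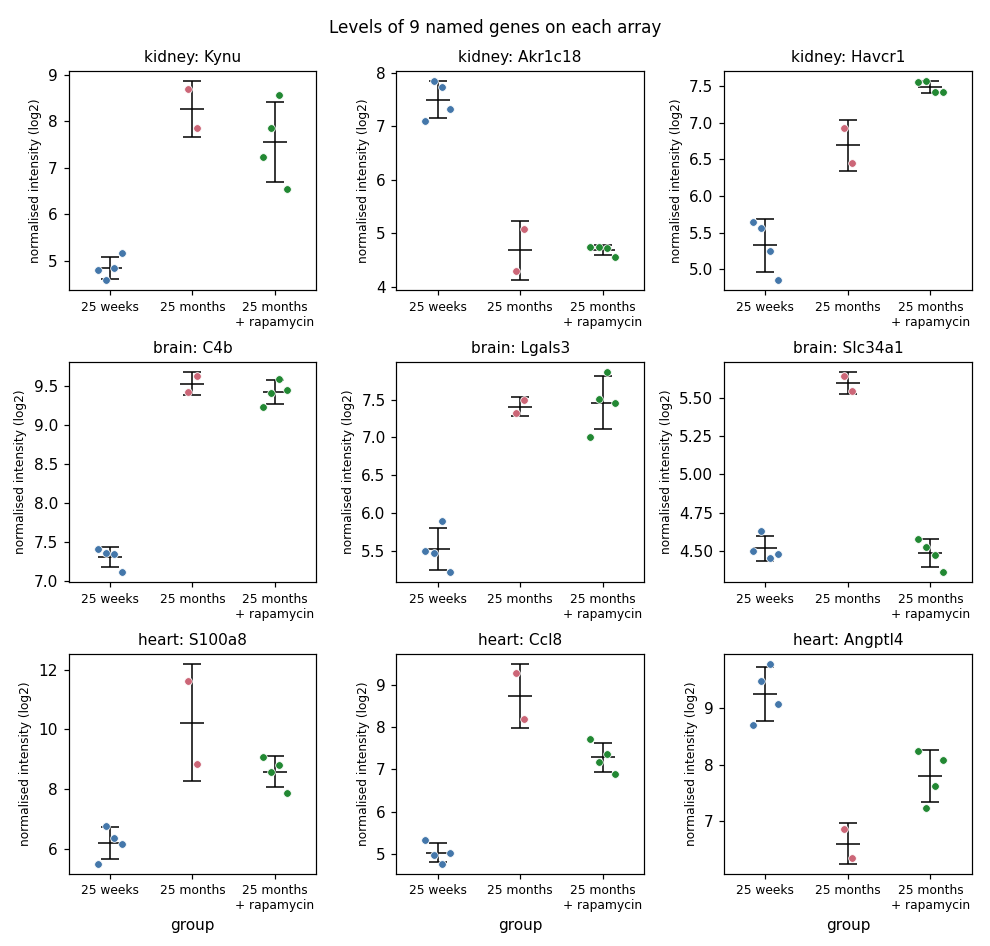
Normalised log2 intensity of 9 named genes on each array (points) by group, 3 genes per tissue, with the mean and SD of each group (black; n = 4, 2 and 4). Brain C4b was log2 2.23 higher in 25-month controls and 2.12 higher in treated mice than in 25-week controls, whereas heart S100a8 was 4.02 (2.64 without 25-month control 1) and 2.38 higher.

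Whether the age difference itself differed between tissues was tested with an interaction term over all 30 arrays, with the mouse as a random effect. Kidney and brain differed at 35 of 12168 probes, 19 with the higher age effect in kidney. Cbr3 had an age effect of log2 3.23 in kidney and 0.17 in brain (adjusted p of the difference = 1.95e-05), Aldh1a1 2.56 and -0.03, and Hsd11b1 -1.57 and 0.16. Kidney and heart differed at 71 of 12288 probes, 31 with the higher effect in kidney. Gsta1 had a fitted value of 3.32 in kidney, where no young array detected it, and 0.22 in heart. Cyp2b10, a drug-metabolising cytochrome, had -1.05 and 1.54. Brain and heart differed at 8 of 12291 probes, 1 with the higher effect in brain. The model has 1 spread per probe over all 30 arrays, so the low kidney array also adds to the error of this contrast. Angptl4 had -0.34 in brain and -2.57 in heart (adjusted p = 0.00556), Kcnk1 -0.19 and 1.99, and Dbp 0.44 and 2.17. For the rapamycin effect limma called 0 probes in each pair of tissues, with 696, 1455 and 306 at an unadjusted p under 0.05 for kidney and brain, kidney and heart, and brain and heart. Without mouse 2 of the rapamycin group's kidney array, the age counts were 437, 494 and 50, and the rapamycin counts 0, 2 and 0. The 2 genes, chosen after their values were seen, were Frzb, a secreted Wnt antagonist (0.85 in kidney and -0.35 in heart), and the chemokine Cx3cl1 (0.52 and -0.45). With a whole mouse left out, the kidney and brain count was 2 without 25-month control 1, 401 without rapamycin mouse 2, and 18, 18, 17 and 15 without young mice 1 to 4. For kidney and heart it was 1, 478, and 29, 42, 38 and 36, and for brain and heart 1 and 47 for those 2 older mice, and 5 and 4 without young mice 3 and 4. Rapamycin counts rose to 3 for kidney and brain without 25-month control 2 or rapamycin mouse 1 and to 1 without rapamycin mouse 2. For kidney and heart they rose to 4 without 25-month control 2 or rapamycin mouse 2, and to 1 without rapamycin mouse 1, 3 or 4.

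Genes that were higher in 25-month than in 25-week controls were shared between tissues. Brain and heart shared 19 genes, where 0.405 would be shared by chance (Fisher's exact test across genes, p = 2.49e-28), among them C4b, Gpnmb, S100a8, S100a9, Lyz1, Oasl2 and Serpina3n. Kidney and heart shared 4, Ccl8, Cxcl13, Dbp and Ms4a6d (0.0451 by chance; Fisher's exact p = 5.31e-08), and kidney and brain shared 1, Ms4a6d (0.0656 by chance; Fisher's exact p = 0.0638). All tissues came from the same 10 mice and genes are not independent, so the chance values and p-values describe the overlap only, and part of it may come from the mice themselves. With a mouse left out of both tissues, brain and heart shared 1 gene without 25-month control 1, 29 without control 2, and 8, 9 and 3 without young mice 1, 3 and 4. Kidney and heart then shared 0 without 25-month control 1, any of the young mice, or rapamycin mouse 1 or 4, 1 without rapamycin mouse 3 and 32 without rapamycin mouse 2. Kidney and brain shared 2 without 25-month control 2, 47 without rapamycin mouse 2 and 0 without any of the others. Of the genes named here, Gpnmb and Ccl8 passed in heart without 25-month control 1, while C4b, S100a8, S100a9, Lyz1, Oasl2, Cxcl13 and Dbp did not (adjusted p = 0.066, 0.11, 0.11, 0.557, 0.574, 0.0707 and 0.113), nor did Ms4a6d and Serpina3n (log2 0.96 and 1.18; adjusted p = 0.403 and 0.35). In kidney without that mouse none of Ccl8, Cxcl13, Dbp and Ms4a6d passed (adjusted p = 0.958, 0.288, 0.958 and 0.958), nor did Dbp without control 2 (0.0588). In brain S100a8 and S100a9 did not pass without control 1 (adjusted p = 0.344 and 0.424), Oasl2 without control 2 (0.0512), and Ms4a6d without either (0.283 and 0.133). With all mice Ms4a6d was the 1 gene that rose in all 3 tissues. Without the low kidney array kidney shared 48 genes with brain and 35 with heart, and 16 rose in all 3 tissues. No gene that fell was shared with all arrays.

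Agreement across genes between the age difference and the difference of treated from young mice was described without reusing an array on both sides. The difference of 25-month controls from 2 of the young mice was correlated with the difference of treated mice from the other 2 young mice, averaged over 6 splits. Pearson's r was 0.539 in kidney (jackknife SE 0.18), 0.303 in brain (0.088) and 0.365 in heart (0.14), and 0.661 in kidney without the low array. Noise and the share of unchanged genes lower r, so it does not measure how much of the age difference remained. Simulated groups with no difference gave at most 0.0325, 0.0849 and 0.0637 in kidney, brain and heart, and 0.0496 without the low array. The age and rapamycin differences share the 2 old controls, which alone makes their correlation negative. It was -0.223 in kidney, -0.601 in brain and -0.533 in heart, against simulated means of -0.667, -0.667 and -0.669, and -0.531 against -0.633 in kidney without the low array. The covariance was -0.0218 in brain (simulated -0.0158 to -0.0125) and -0.0361 in heart (simulated -0.0284 to -0.024). In kidney it was -0.0313 with all arrays (simulated -0.1 to -0.09) and -0.0468 without the low array (simulated -0.0215 to -0.018). Genes are not independent replicates, and no p-value was computed. The simulations drew each gene independently, with 1 spread per gene for all groups. Genes that vary together would widen the simulated ranges, and a larger or smaller spread in the old controls would move them. In kidney with all arrays the low treated array adds to that shared spread, and the simulated range was more negative than without it. The kidney value with all arrays therefore cannot be read against its range. Values outside these ranges therefore do not decide whether rapamycin reversed age differences. With each mouse left out in turn the age and rapamycin correlation ranged from -0.531 to -0.131 in kidney, and -0.531 was the value without rapamycin mouse 2.

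**Figure D3:**
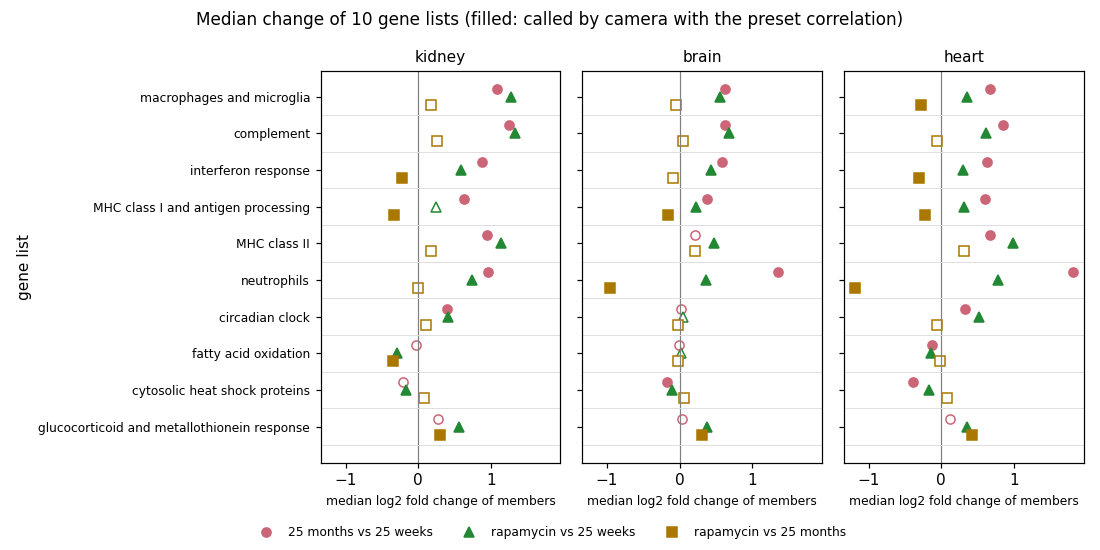
Median log2 fold change of the measured members of 10 gene lists in each tissue for 3 comparisons, filled where camera called the list with the preset correlation. Neutrophil genes had medians of 1.36 with age and -0.95 with rapamycin in brain, and 1.81 and -1.19 in heart. Without 25-month control 1 these were 1.08 and -0.404 in brain and 1.25 and -0.115 in heart, and without control 2 they were 2.09 and -1.67, and 3.64 and -2.48. With an estimated correlation these 4 calls were lost (adjusted p = 0.153, 0.267, 0.156 and 0.642), and 0 lists were called in heart or for rapamycin in any tissue.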

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

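Tests of kidney RNA on brain arrays, of Prg2 and of both neutrophil explanations, given among the other observations, and the low-array comparison of probe pairs in its final form were chosen after the result was seen. Among them, the rank correlation of kidney transcripts had its prediction written before its value was seen. Chance gives a sample this far from the other 3 in about 1 in 20 groups, and 18 pairs of a group of 4 arrays and an array measure were tested. Median signal, probes detected and median correlation were each tested on the same groups, so these tests are not independent.

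The kidney array of rapamycin mouse 2 lay far from the other 3 arrays of its group, with 9989 probes detected (gap over range 0.833) and a median correlation of 0.8585 with the other kidney arrays (0.973). The heart array of young mouse 2 lay apart from its group as well, with 12376 probes detected (0.83) and a median correlation of 0.9912 (0.833). Age effects differed between kidney and brain at 35 probes, between kidney and heart at 71 and between brain and heart at 8, each by a test of the difference itself.

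Single arrays of named genes lay apart from the other 3 of their group in 14 of 228 gene groups tested, about the share that chance gives (values are log2 intensities). In kidney these were Akr1c18 in rapamycin mouse 4 (4.55), Mtor (7.47) and Slc34a3 (7.54) in rapamycin mouse 2, Pla1a in rapamycin mouse 1 (8.12), S100a8 in rapamycin mouse 4 (5.6) and Slc22a7 in young mouse 1 (7.71). In brain they were Ch25h in young mouse 4 (4.54) and in rapamycin mouse 1 (5.67). In heart they were Ciart (6.95), Oasl2 (7.71), Per2 (8.79) and Ucp1 (6.11) in rapamycin mouse 3, and H2-Ab1 (9.74) and Lyz1 (11.9) in young mouse 2.

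A state of the whole mouse was weighed for the low kidney array, and the tables argue against one that shifts transcripts broadly in every tissue: its heart array had a median correlation of 0.9947 with the other heart arrays, the highest of 10, and its brain array had 0.9948, at rank 2 from the lowest of 10 (lowest 0.9941). Some transcripts on these arrays did stand apart, as 19 of 21 kidney transcripts were higher on its heart array with a median of 0.415 (highest of the other heart arrays 0.0171) and Gh, Prl and Pomc were at 13.72, 11.41 and 8.946 on its brain array, the highest of 10, so a narrower difference of this mouse or its samples stays open. A failed array or degraded RNA stays open as a candidate explanation: probes of 1 gene deviated together on this array with a correlation of 0.338 (bootstrap 0.276 to 0.397 over 1000 draws), and the other 9 kidney arrays had 0.341 to 0.673. The 0.673 came from both old controls, whose deviations mirror each other because their group holds 2 arrays. The reference and the bootstrap margin were set after the first values were seen, and by the correlation alone the explanation stays open. Deviations on this array had an SD of 1.21, against 0.181 to 0.31 on the other 9. Those not shared by probes of 1 gene were therefore far larger here, which a correlation does not show. This would go with a failed array or degraded RNA, but it was not tested against other causes.

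Whether the counts of treated against young mice could arise by chance was tested by splitting the same arrays in all 35 ways. In kidney 1 of 35 splits, the real one, gave as many as 51 probes and the highest other gave 0. The same held in brain (158 real, 0 highest other), in heart (130 and 0) and in kidney without the low array (1156 and 0). Chance is not excluded, because with 35 splits no share under 1 of 35 can arise. Mixed splits also move any difference between young and treated mice into the spread, which lowers their counts. The comparisons with 2 old controls have too few arrays in 1 group for this test.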

How the results depend on the processing

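Among the 97 calls of named genes, 1352 values were computed under other settings, and 965 stayed past the threshold, 387 kept their direction below it and 0 reversed. Slc34a1, Spink1 and Prg2 in brain left the detection filter with a 25-month control left out, and keeping the filter of all arrays was chosen after seeing this. Of 184 gene list calls, 0 changed the sign of their median under 3 other normalizations. Counts moved by over 1.5 times as follows, and the cause was not tested except where fewer arrays or probes entered a fit. Settings not named for a count left it within that margin.

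With no background correction, kidney gave 0 probes for age (13 in the report) and 30 for treated against young mice (51), and brain gave 0 for rapamycin (4). With median scaling, kidney age gave 1, brain rapamycin 20 and heart treated against young 255 (130). The authors' values gave 80 for kidney treated against young, 9 for brain rapamycin, 45 for heart age (86), 3 for heart rapamycin (0), 56 for heart treated against young, and 3 for kidney rapamycin without the low array (0). Probes detected on all arrays gave 6 for kidney age, 0 for brain rapamycin and 52 for heart age. With no filter the counts were 0 for kidney age, 2 for brain rapamycin, 43 for heart age and 79 for heart treated against young. A variance trend with robust moderation gave 188 for brain age (123).

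Array weights gave 1470 for kidney age, 3 for kidney rapamycin (0), 2931 for kidney treated against young, 405 for brain treated against young (158), 326 for heart age, 212 for heart treated against young, and 2800 for kidney treated against young without the low array (1156). Only the arrays of the compared groups gave 1491 for kidney age, a fit that drops the low array. The replicate number as a block gave 0 and 4 for kidney age and treated against young, 72 and 2 for brain age and rapamycin, and 19 and 55 for heart age and treated against young. Replicate numbers do not pair mice, as same-number residuals had median correlations of 0.014, 0.068 and -0.046 in kidney, brain and heart. Grouping by titles swaps both control groups, so rapamycin gave 51, 158 and 130 and treated against young 0, 4 and 0 in kidney, brain and heart.

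For the tissue differences in age effect, leaving the mouse out of the model gave 21 for kidney and brain (35) and 41 for kidney and heart (71). No filter gave 99, 156 and 32 for kidney and brain, kidney and heart, and brain and heart (8), and the authors' values gave 58 for the first pair and 18 for the last. Without the low kidney array, chosen after seeing the data, they were 437, 494 and 50. For the rapamycin effect no filter gave 2, 4 and 1, the authors' values 2, 8 and 1, and leaving out the low array 2 for kidney and heart. Genes shared by kidney with brain and heart rose from 1 and 4 to 48 and 35 without that array. With a mouse left out of both tissues, also chosen after seeing the data, shared genes ranged over 0 to 47 for kidney and brain, 0 to 32 for kidney and heart, and 1 to 29 for brain and heart (19), where values over 1.5 times away were 1, 3, 8, 9 and 29. Lists called for age, rapamycin and treated against young fell with an estimated correlation from 16, 13 and 18 to 5, 0 and 4 in kidney, from 13, 10 and 15 to 3, 0 and 3 in brain, and from 15, 8 and 19 to 0, 0 and 0 in heart.

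With each mouse left out in turn, counts for age, rapamycin and treated against young ranged over 0 to 1315, 0 to 2 and 2 to 1156 in kidney, 23 to 133, 0 to 21 and 62 to 440 in brain, 5 to 214, 0 to 36 and 30 to 267 in heart, and 87 to 1615, 0 to 155 and 431 to 2318 in kidney without the low array. With 1 old control left, that sample is assumed to vary like the other groups. The error of such a fit is also wider, so a call lost there need not mean a smaller difference. Medians of called lists, added after seeing the data, moved by over 1.5 times or changed sign without some mouse for 9 of 16, 13 of 13 and 8 of 18 lists in kidney, 7 of 13, 9 of 10 and 4 of 15 in brain, 12 of 15, 6 of 8 and 7 of 19 in heart, and 12 of 22, 12 of 14 and 3 of 21 in kidney without the low array. Signs changed for 1, 2 and 0 of these in kidney, 0 in brain, 0, 2 and 1 in heart, and 1, 3 and 0 in kidney without the low array. Age effect differences ranged over 2 to 401, 1 to 478 and 1 to 47 for kidney and brain, kidney and heart, and brain and heart, and rapamycin effect differences over 0 to 3, 0 to 4 and 0 to 0. The correlation of the age difference with the difference of treated from young mice ranged over 0.428 to 0.661, 0.226 to 0.319 and 0.273 to 0.449 in kidney, brain and heart. That of age with rapamycin ranged over -0.531 to -0.131, -0.704 to -0.521 and -0.729 to -0.441. A slide block was not run. Signal over background limits dim transcripts. In simulated data of the age comparison with 200 changed probes, a change of log2 0.5 was found for 0.896% of probes in kidney, 45.1% in brain and 20.9% in heart.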

Other observations

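Tests of kidney RNA in brain and of Prg2, and both tests of the neutrophil markers, were chosen after the result was seen. Only the rank correlation of kidney transcripts below had its prediction written before its value was seen. Levels here are log2 intensities normalised over all 30 arrays, and the genes of the next paragraph were chosen after their values were seen.

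Pituitary hormone transcripts varied widely between brain samples. Gh, which encodes growth hormone, was undetected on both 25-month control arrays (4.32 and 4.34), detected on all 4 treated arrays (7.90 to 13.7) and ranged from 4.46 to 10.4 on young arrays. Prl, which encodes prolactin, was at 4.26 to 4.30 in old controls, 5.69 to 11.4 in treated mice and 4.30 to 9.15 in young mice. Cdhr1, a cadherin-related gene of olfactory bulb neurons, was at 5.92 and 8.30 in old controls, 8.26 to 8.91 in treated mice and 6.15 to 8.02 in young mice.

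The clock output gene Dbp passed the test against young mice in kidney and heart of both 25-month groups, although for kidney of old controls it passed in 1 of the 10 fits with a mouse left out and for heart of old controls not without control 1. It was at 8.70 to 9.22 in young kidney, 10.3 to 10.7 in old controls and 10.3 to 10.8 in treated mice, and in heart at 7.90 to 8.84, 10.4 to 10.8 and 10.0 to 10.7. Nfil3, a repressor of clock output genes, was at 9.08 to 9.26 in young heart, 8.46 to 8.49 in old controls and 7.57 to 8.66 in treated mice. In kidney Nfil3 was at 7.59 to 8.48 in young mice, 7.06 to 7.31 in old controls and 6.83 to 8.47 in treated mice, and the clock activator Arntl at 6.004 to 6.675, 5.602 to 5.651 and 5.288 to 6.515, with the highest treated value of both on the low kidney array. Neither passed there with all arrays, and without that array both were lower in treated than in young mice (Nfil3 by 1.141 ± 0.207 and Arntl by 0.845 ± 0.162). The hour of tissue collection was not given in the sources used here. Genes that respond to glucocorticoids had positive medians with rapamycin in kidney (0.30), brain (0.30) and heart (0.43), with camera adjusted p = 0.0063, 1.01e-05 and 7.7e-07, and adjusted p = 0.446, 0.267 and 0.642 with an estimated correlation. The kidney median was 0.47 without 25-month control 1 and the brain median 0.169 without control 2.

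Slc34a1 was at 5.30 to 5.39 on the brain arrays of 25-month controls, at 4.35 to 4.57 on the other brain arrays and at a mean of 14.1 in young kidney, and a trace of kidney RNA may account for this and for Spink1, likewise raised there. Other kidney transcripts, above log2 12 in young kidney and detected on at most 2 brain arrays, rose there by medians of 0.209 and 0.0919. The highest of the other 8 arrays had -0.00142. Across 16 of them the rise followed that on the heart array of rapamycin mouse 2 (rank correlation 0.559, two-sided permutation p = 0.0275). The fixed proximal tubule list did not show it, with medians of -0.00607 and 0.0346 on those arrays. Umod was at 13.94 to 13.99 in kidney of the 25-month controls. On their brain arrays it was undetected, at 4.519 and 4.726 against 4.341 to 4.476 on the others. Kap, at 11.83 to 13.07 in that kidney, was at 4.636 and 5.259 on those brain arrays and 4.343 to 4.471 on the others. For Prg2 the tables argue against kidney RNA, since its level in kidney minus that in brain was at most -0.585 in the same mice, and what raised it stays open.

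Neutrophil markers were lower on treated than on control 25-month arrays of brain and heart, with medians of -0.954 and -1.19, while in kidney 3 of 6 were lower (median 0.000936, and 0.324 and -0.42 without old controls 1 and 2). A single control mouse may set the difference: with the normalization of all arrays kept, the medians without old control 1 were -0.457 in brain and -0.19 in heart, and without old control 2 they were -1.62 and -2.08. More blood in the control samples was weighed too, and red cell genes were lower by medians of -0.216 in brain, -0.164 in heart and -0.597 in kidney, which became 0.0198, 0.0198 and -0.297 without old control 1 and -0.5, -0.197 and -0.725 without old control 2. Neither explanation can be decided with 2 control mice, and an effect of treatment stays open as untested.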
